A study of Mus musculus with 11 samples.

How the data were processed

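The series profiled a mouse T-cell acute lymphoblastic leukaemia line by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels' protocols, the cells were transduced with an epitope-tagged Zmiz1 and with an activated Notch1, and doubly marked cells were sorted. Zmiz1 is a PIAS-like coactivator, ICN1 is the intracellular, activated form of Notch1, and Rbpj is the DNA-binding protein through which ICN1 acts. There were 2 transduced lines, named for the tag and the Notch1 construct. Flag-Zmiz1/L1601PDP is called the Flag line here, and HA-Zmiz1/DEGFDLNRDP the HA line. The 11 samples each formed a group of their own: Flag-Zmiz1, ICN1, Rbpj, H3K4me1, H3K4me3, H3K27me3, H3K27ac and input in the Flag line, and HA-Zmiz1, ICN1 and input in the HA line. With 1 library per target and line there were no replicates, so no difference could be set against a spread between replicates. Chromatin for the factor samples was fixed with DSG and formaldehyde, and that for the histone samples with formaldehyde alone, per the labels' protocols.

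Peaks of the 5 factor libraries had been called with MACS version 2.0.10.20120913 against the input of the same line, per the file headers, with a p limit of 1e-05, 1 tag kept per position and local background windows of 1000 and 10000 bp. The submitters' processing notes name Bowtie 0.12.7, FastQC 0.10.0, MACS2 2.0.10, SICER 1.1, HOMER 4.2 and the mm10 build. The headers of the HA line name pooled reads, so any repeat precipitations in that line cannot be compared. Each deposited peak carries a pileup signal at its summit, a fold enrichment over the local input background and a −log10 p, all computed by the authors. Histone segments came with deposited read counts for the precipitation and the control, a fold over the control (a ratio), a p-value and a false discovery rate. Segment widths were multiples of 200 bp, and the highest false discovery rate in any list was 0.001. These scores were used only to describe, rank or filter regions within a list. Fragment lengths in the headers ran from 52 to 63 bp at a tag length of 52 bp, and may reflect the length of the reads and not that of the fragments, which bears on peak widths, pileups and the input ratio below. Median peak widths were 78 to 129 bp.

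The local input background of each peak was recovered from the deposited values as (pileup + 1) / fold − 1, and divided by the library's mean background, which is fragment length times filtered tags over the effective genome size. A peak at 10 or more times that mean is called a high-input peak, and the others low-input peaks. This limit was chosen after seeing the data.

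Peaks were compared by overlap of at least 1 bp. Each share has an exact (Clopper-Pearson) 95% interval, which covers counting error only and takes peaks as independent, which neighbouring peaks are not. Overlaps were tested by placing the peaks of a list at random 1000 times on their own chromosomes, between the lowest and highest coordinate seen in any list or the gene table. The smallest one-sided p is 0.000999 and the smallest two-sided p is 0.002. Assembly gaps were not excluded, which lowers the random share. Shares in separate lists were compared with Fisher's exact test (two-sided). It takes the lists as independent, which lists that share sites are not. Zmiz1 at Rbpj peaks with and without ICN1 was tested with the Cochran-Mantel-Haenszel test over 10 bins of Rbpj fold. Fold enrichments of shared and unshared peaks were compared by the difference of medians with 100000 permutations. Such p-values describe these libraries, not the conditions. The factor libraries of a line share an input library, so part of an overlap within a line can come from that input. P-values were adjusted by the Benjamini-Hochberg method within each family.

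Gene positions came from a RefSeq table of the GRCm38.p6 assembly, the same build as mm10, with 21887 protein-coding genes. The table gives the span of a gene but not its strand or exons, so distances run to the nearer end of a gene span in place of the transcription start. Exon, intron and untranslated-region annotation and motif searches were not used here. The 9 gene lists hold 185 genes, all matched by symbol. A list was scored by the share of its genes with a peak within 50 kb of either end, against 10000 random lists of the same size from the 10192 genes with an H3K4me3 segment over an end. There were 45 such tests. The smallest two-sided p is 0.0002.

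Within a list, strength was ranked by −log10 p. The genes named were set by a rule that takes the gene nearest each of the 15 strongest shared ICN1 peaks per line, up to 20 list genes with a Zmiz1 and an ICN1 peak within 50 kb, a fixed set of Notch-pathway genes, the gene nearest the 5 strongest peaks of each list, and the first 4 developmental regulators and housekeeping genes. An item that the rule covers is not reported here. The rule, the 9 gene lists, the tests and a first set of alternatives were fixed before the data were examined. These alternatives were a stricter overlap, summits within 200 bp, a p limit of 1e-10, the 100 strongest peaks, placement within histone segments, autosomes only, other windows of 500 bp and 5 and 200 kb, other bins, other gene pools and the upper 50% of the segments by fold. Removing high-input peaks, placement with the library labelled H3K27me3, no matching on Rbpj fold, matching on gene length and Zmiz1 lists of equal length in the comparison of the lines were added after seeing the data.

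The tests were tested on simulated data. Over 100 simulations, lists of 82 and 414 peaks (Flag and HA line) with true overlaps of 30.5% and 30.0% gave mean shares of 30.5% and 30.0%. Those overlaps were planted by copying peak positions, so the shares were set by design, and the other peaks were placed evenly over the genome, as in the test. How the placement test behaves with clustered peaks or high-input regions was therefore not examined. For the Rbpj comparison with 20993 peaks and a true odds ratio of 5, the median estimate was 5.16, and 94% of the intervals held the true value. With an odds ratio of 1, the matched test called 1% of the simulations and the unmatched test 60%. The simulated chances of ICN1 and Zmiz1 depended on the bin alone. So these simulations cannot show whether matching removes effects of Rbpj fold within a bin. For a list of 25 genes at 4 times the share of the pool, 65% of simulations were called. A shift of 2 in median fold between shared and unshared HA-line ICN1 peaks was called in 100% of 20 simulations. The difference in the data was 0.203, and shifts of that size were not simulated, so the power to detect them is unknown. A further list of 32 neuronal genes and another of 32 liver, muscle and gut genes were written after the peak lists had been seen, leaving out genes noticed there. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.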

Results

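The 5 factor lists differed widely in length at similar depth. MACS listed 581 Flag-Zmiz1 peaks from 15429394 filtered tags and 4984 HA-Zmiz1 peaks from 15322650. ICN1 gave 82 peaks in the Flag line from 15377221 tags and 414 in the HA line from 13450671. Rbpj, profiled in the Flag line, gave 20993 peaks from 19048270 tags. The inputs held 36.4 M filtered tags in the Flag line and 26.8 M in the HA line. There were no replicates. The 4 histone libraries of the Flag line gave 46130 segments over 197 Mb for H3K4me1, 26767 over 66.3 Mb for H3K4me3, 33646 over 131 Mb for the library labelled H3K27me3 and 25172 over 153 Mb for the library labelled H3K27ac. The read totals of the histone libraries are unknown. High-input peaks made up 53 of the 82 ICN1 peaks of the Flag line (64.6%, 95% interval 53.3 to 74.9), 42 of the 581 Flag-Zmiz1 peaks, and 32 of 4984, 32 of 414 and 48 of 20993 peaks in the HA-Zmiz1, HA-line ICN1 and Rbpj lists.

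The series asked whether Zmiz1 acts with Notch1 on chromatin. In the HA line, 302 of 414 ICN1 peaks (72.9%, exact 95% interval 68.4 to 77.2) overlapped an HA-Zmiz1 peak, against a mean of 0.0601% in random placements (one-sided p = 0.000999, the smallest possible). Among the 100 strongest peaks of each list the share was 16.0%. The strongest shared ICN1 peak, by −log10 p, lay inside Ctnnd2, a catenin gene, on chromosome 15 from 30975107 to 30975367, with an ICN1 fold of 43.0 and an HA-Zmiz1 fold of 11.8. Others lay inside Stk3, a kinase of the Hippo pathway (ICN1 fold 20.7, HA-Zmiz1 fold 17.2), inside Notch3, a Notch receptor (chromosome 17, 32164276 to 32164545, 19.2 and 14.4), inside Ccnd3, the cyclin D3 gene (17.2 and 14.6), and inside Lpp (ICN1 fold 24.1). A shared peak 163 kb from Lef1, a T-lineage transcription factor, had an ICN1 fold of 18.2 and an HA-Zmiz1 fold of 14.1. The 15 strongest shared peaks also included sites inside Rec114, Naxd, Nck2 and Zbtb11 and near Gm266, Dennd2d, Rhoh and Irak1bp1. Seen from Zmiz1, 295 of 4984 HA-Zmiz1 peaks (5.92%) carried ICN1. Removing high-input peaks left 278 of 382 ICN1 peaks shared (72.8%).

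In the Flag line, 42 of 82 ICN1 peaks (51.2%, exact 95% interval 39.9 to 62.4) overlapped a Flag-Zmiz1 peak (random mean 0.00244%, one-sided p = 0.000999). All 42 were high-input peaks. They lay at 11 places: chromosome 17 from 39843204 to 39848804 with 11 shared peaks, chromosome 9 from 3000028 to 3035885 with 8, chromosome 2 from 98662252 to 98667294 with 8, chromosome 14 from 19415716 to 19419412 with 8, and 7 others with 1 each. The nearest genes of the 15 strongest were far away: Alkbh8 at 308 kb or more, Lrrc4c at 1031 kb or more, Gm2244 at 115 kb or more and Rab10 at 137 kb. Of the 29 low-input ICN1 peaks of the Flag line, 0 overlapped a low-input Flag-Zmiz1 peak (95% interval up to 11.9%), while 19 (65.5%, 45.7 to 82.1) overlapped a low-input HA-Zmiz1 peak.

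**Figure D1:**
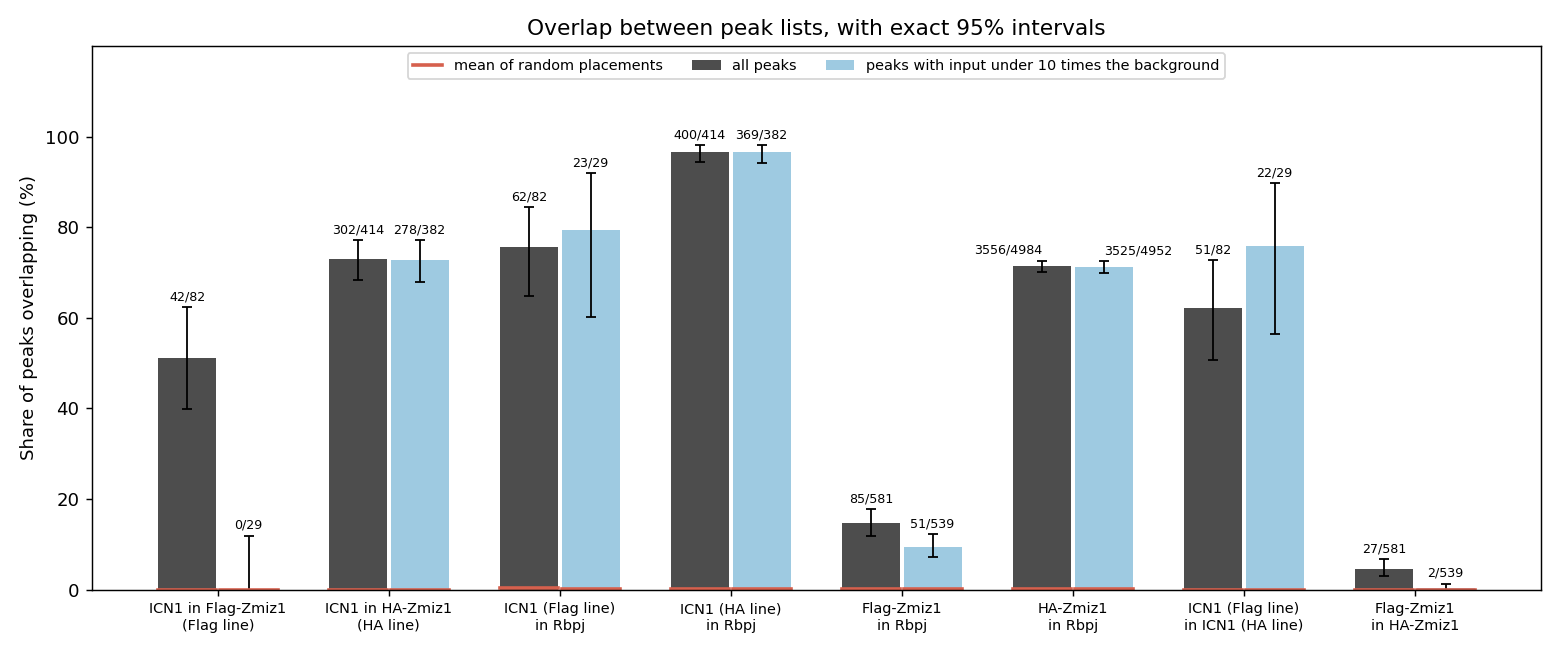
Share of peaks of a list (y axis, %) overlapping a second list, for all peaks (grey) and low-input peaks (blue), with exact 95% intervals, counts above the bars and the mean of random placements as red lines. The ICN1 overlap with Flag-Zmiz1 went from 42 of 82 to 0 of 29 without high-input peaks, and that with HA-Zmiz1 from 302 of 414 to 278 of 382.

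ICN1 acts through Rbpj, and nearly all ICN1 sites of the HA line held Rbpj: 400 of 414 peaks (96.6%, 95% interval 94.4 to 98.1) against a random mean of 0.252%. In the Flag line the share was 62 of 82 (75.6%, 64.9 to 84.4), and 23 of 29 among low-input peaks (79.3%). HA-Zmiz1 met Rbpj at 3556 of 4984 peaks (71.3%, 70.1 to 72.6), and Flag-Zmiz1 at 85 of 581 (14.6%, 11.9 to 17.8), or 51 of 539 among low-input peaks (9.46%). For each of these comparisons the one-sided p of random placement was 0.000999. With the 100 strongest peaks of each list, the Flag-Zmiz1 overlap with Rbpj was 0 of 100 and did not pass. Among the HA-line ICN1 peaks, 299 carried HA-Zmiz1 and Rbpj, 101 Rbpj without HA-Zmiz1, 3 HA-Zmiz1 without Rbpj and 11 neither. The strongest Rbpj peaks, by −log10 p, lay in or near Gipc1 (fold 59.0), Dtx1, an established Notch target (chromosome 5, 120685632 to 120686211, fold 49.7), Gk5 and Rpl23, and 199 kb from Eef2kmt. The Dtx1 site also had an ICN1 peak in the HA line (fold 10.8) and an HA-Zmiz1 peak (fold 4.79).

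At Rbpj sites, HA-Zmiz1 was more frequent where HA-line ICN1 was present. In the HA line, 294 of 387 Rbpj peaks with ICN1 carried HA-Zmiz1 (76.0%) and 3260 of 20606 without ICN1 (15.8%). Matched on Rbpj fold, the odds ratio was 11.5 (Cochran-Mantel-Haenszel 95% interval 8.99 to 14.7). Without matching it was 16.8 (Fisher's exact p = 1.4e-147, two-sided). The top bin of Rbpj fold, from 10.3 to 59.0, held 242 of the 387 Rbpj peaks with ICN1. Differences of Rbpj fold within that bin were not matched. The share of Rbpj peaks with HA-line ICN1 was 11.5% in the top bin of Rbpj fold and 1.33% in the lowest. HA-Zmiz1 was found at 30.9% and 14.1% of the Rbpj peaks of those bins. Neither share rose steadily: ICN1 was at 0.190% in bin 4 and HA-Zmiz1 at 11.1% in bin 3. High-input peaks were kept in these bins, and the lowest bin ran from a fold of 1.81 to 4.53. Without them, 361 Rbpj peaks carried HA-line ICN1 in place of 387. The shares per bin were not computed without them, so how far the 1.33% rests on high-input peaks was not determined. In the Flag line the odds ratio was 564 (255 to 1249), with Flag-Zmiz1 at 31 of 58 Rbpj peaks with ICN1, but 0 of 23 low-input Rbpj peaks with ICN1 carried Flag-Zmiz1. Rbpj was profiled in the Flag line alone, so the HA-line comparison joins libraries of both lines.

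**Figure D2:**
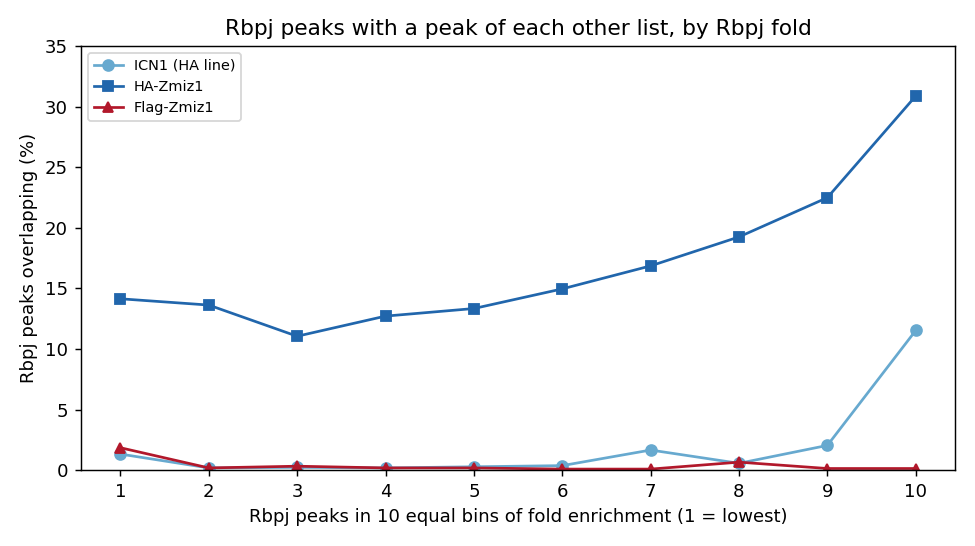
Share of Rbpj peaks (y axis, %) overlapping HA-line ICN1, HA-Zmiz1 or Flag-Zmiz1 peaks, over 10 equal bins of Rbpj fold enrichment (x axis, lowest to highest). HA-Zmiz1 was at 14.1% of the peaks in the lowest bin and 30.9% in the highest, and HA-line ICN1 at 1.33% and 11.5%. Neither share rose steadily between them. High-input peaks are kept.

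Myc is a growth regulator and a Notch target in T-cell leukaemia. Within 2 Mb toward higher coordinates from Myc (chromosome 15, 61985341 to 61990361), there were 16 HA-Zmiz1 peaks, 26 Rbpj peaks, 3 ICN1 peaks in the HA line, 1 ICN1 peak in the Flag line and 0 Flag-Zmiz1 peaks. The single Flag-line ICN1 peak, from 63255675 to 63256072, was the strongest of its list by −log10 p (fold 22.2). It lay 1.27 Mb from Myc and coincided with ICN1 in the HA line (fold 26.6), HA-Zmiz1 (fold 20.2) and Rbpj (fold 19.3). A second HA-Zmiz1 site, from 63279576 to 63280195 (fold 20.1), covered 2 ICN1 peaks of the HA line (folds 5.84 and 6.38). By −log10 p those sites ranked 2 and 3 among the 4984 HA-Zmiz1 peaks. Both lay in H3K4me1 and H3K4me3 segments and in segments of the library labelled H3K27me3. At Myc itself, 6 Rbpj peaks and 1 Flag-Zmiz1 peak lay within 50 kb.

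**Figure D3:**
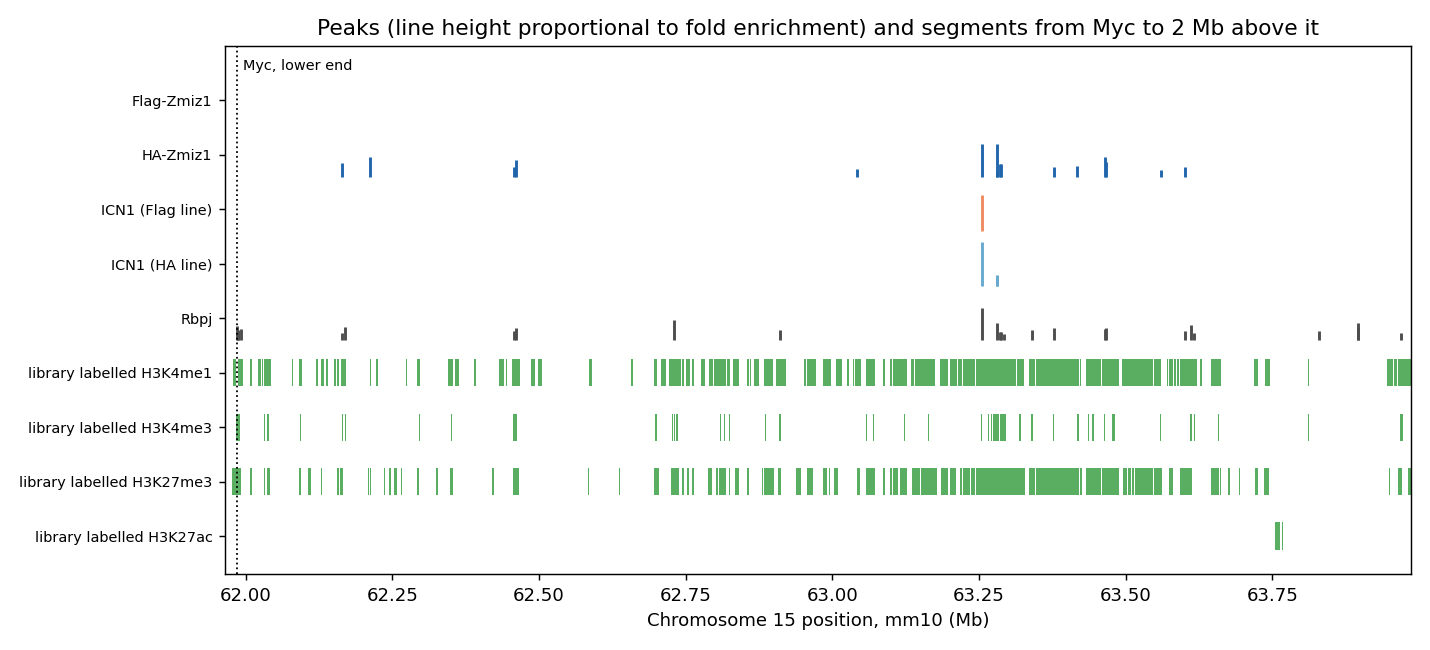
Chromosome 15 from Myc to 2 Mb above it (x axis, mm10, Mb), with factor peaks as lines whose height is proportional to the fold enrichment and histone segments as bars, 1 row per library. The tallest ICN1 lines of both lines stand at the same site, 1.27 Mb from Myc, where HA-Zmiz1 and Rbpj have peaks and Flag-Zmiz1 has none.

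Genes of the T-cell receptor and T-cell surface stood out near HA-line peaks. HA-Zmiz1 lay within 50 kb of 24 of 25 such genes (96.0%, random lists 41.2%) and ICN1 within 50 kb of 12 of 25 (48.0%, random lists 5.11%), each with an adjusted p of 0.00225. With 5 kb windows the ICN1 result did not pass (3 of 25, adjusted p of 0.0709). Examples were Cd8a, a co-receptor gene (HA-Zmiz1 fold 14.3, ICN1 fold 7.19), Cd4 (15.5 and 4.79), Cd2 (12.1 and 8.86), and Lat, an adaptor of receptor signalling (13.3 and 8.15). The Cd3d, Cd3e and Cd3g genes share a single ICN1 peak, and so do Cd8a and Cd8b1, so these genes are not independent. The other genes with both factors within 50 kb, not always at the same site, included Cd247, Dntt and Ptprc. At Cd247 the single HA-Zmiz1 summit (165845185) and the single ICN1 summit (165816546) lay apart. Of the T-lineage regulators, 19 of 26 lay near HA-Zmiz1 (73.1%, adjusted p of 0.0105) and 5 of 26 near ICN1 (19.2%, random lists 5.14%), which did not pass (adjusted p of 0.0945). These results depended on the setting: the HA-Zmiz1 one did not pass with windows of 5 kb (10 of 26) or 200 kb (23 of 26), and the ICN1 one passed with 200 kb (10 of 26, adjusted p of 0.0405) and against lists from all coding genes (adjusted p of 0.018). Those 5 were Tcf7 (HA-Zmiz1 fold 17.6, ICN1 fold 8.56), Ets1, Ikzf1, Gfi1 and Bcl6. At Bcl6 the single HA-Zmiz1 summit (23988626) and the single ICN1 summit (24021902) lay apart.

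Of the Notch targets, 7 of 26 lay near HA-line ICN1 (26.9%, random lists 5.22%, adjusted p of 0.0105). That did not pass with peaks at p of 1e-10 or less (4 of 26, adjusted p of 0.108) or with 5 kb windows (1 of 26). Near HA-Zmiz1 there were 11 of 26 (42.3%, random lists 41.1%), which did not pass (adjusted p of 1). Genes with both within 50 kb, not always at the same site, included Nrarp, Dtx1, Notch3, Igf1r and Ccnd3. At Nrarp the single HA-Zmiz1 summit (25228805) and the single HA-line ICN1 summit (25168131) lay apart. Over these 3 lists of Notch and T-cell genes, 23 genes had a Zmiz1 peak and an ICN1 peak of either line within 50 kb, and the naming rule stopped at 20. Igf1r, a growth factor receptor gene, also had the only Flag-line ICN1 peak near a Notch target (fold 6.86). That peak lay 38.2 kb from the end of Igf1r and 1.98 kb from Fam169b. Il2ra, the interleukin-2 receptor alpha chain, had 7 HA-Zmiz1 peaks (best fold 12.4) and no ICN1 peak. Lef1 had 1 HA-Zmiz1 peak within 50 kb (fold 7.83). Notch1 and Ptcra had Rbpj peaks alone, as did Zmiz1 itself, and Hes1, a classical Notch target, had no factor peak within 50 kb. Developmental regulators were below random lists for HA-Zmiz1 (2 of 30, random lists 41.1%) and Rbpj (10 of 30, random lists 94.97%), each with an adjusted p of 0.00225. The random lists hold genes with H3K4me3 at an end, as only 3 of these 30 have, which sets part of the gap; against all coding genes the random shares were 27.2% (adjusted p of 0.0425) and 66.9% (adjusted p of 0.00386). The HA-Zmiz1 result did not pass with peaks at p of 1e-10 or less (adjusted p of 0.193) or with 5 kb windows (0 of 30, adjusted p of 0.0709), while the Rbpj result passed in every setting. Of the other lists, B-cell genes (5 of 12 near HA-Zmiz1), myeloid genes (6 of 12), housekeeping genes (10 of 20), MYC-axis and growth genes (8 of 18) and the Zmiz, PIAS and Notch complex genes (5 of 16) did not pass for any factor with 50 kb windows and this gene pool. Near Rbpj, B-cell genes (4 of 12) and myeloid genes (5 of 12) were below random lists with 5 kb windows, and the last 3 of these lists were above random lists from all coding genes. Notch targets near Rbpj (21 of 26, 80.8%) lay below random lists without passing (adjusted p of 0.0945); they passed below with 5 kb windows (14 of 26, adjusted p of 0.0225) and lay above random lists from all coding genes without passing (random lists 66.9%, adjusted p of 0.458). No list passed for Flag-Zmiz1 or Flag-line ICN1, where 2 of 26 and 1 of 26 Notch targets had a peak.

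The histone context differed between the Zmiz1 lists of the lines, where tag, Notch1 construct and library change together. All histone libraries came from the Flag line, so HA-line peaks were set against chromatin of the other line. HA-Zmiz1 peaks lay in H3K4me3 segments at 93.2% (95% interval 92.4 to 93.9), in H3K4me1 segments at 82.8% and in segments of the library labelled H3K27me3 at 93.6%, against random means of 2.94%, 8.59% and 5.75%. HA-line ICN1 was alike, at 89.1%, 78.3% and 89.4%, and Rbpj was at 87.3%, 57.8% and 86.2%. Flag-Zmiz1 peaks lay in these segments at 9.29%, 15.8% and 11.7%. Flag-line ICN1 peaks lay there at 63.4%, 46.3% and 51.2%, and the 29 low-input peaks of that list at 79.3%, 82.8% and 79.3%. All these shares were above random placement (two-sided p of 0.002, the smallest possible). In the upper 50% of segments by fold, Flag-Zmiz1 no longer passed in H3K4me3 (2.58%, two-sided p of 0.23) or in the library labelled H3K27me3 (4.99%, two-sided p of 0.0839). In the same upper 50%, HA-Zmiz1 lay in H3K4me3 at 48.3%, HA-line ICN1 at 43.5% and Rbpj at 67.5%. In H3K4me1 these shares were 74.2%, 70.0% and 40.7%, and in the library labelled H3K27me3 81.4%, 77.3% and 73.9%. Each was still above random placement (two-sided p of 0.002). Among low-input Flag-Zmiz1 peaks the shares were 5.19% in H3K4me3 (two-sided p of 0.00599), 15.4% in H3K4me1, 9.83% in the library labelled H3K27me3 and 9.09% in that labelled H3K27ac (random mean 6.82%, two-sided p of 0.04995). The library labelled H3K27ac held 1.93% of HA-Zmiz1 and 5.31% of Rbpj peaks, both below random placement (two-sided p of 0.002), though Rbpj did not pass in the upper 50% of its segments (3.73%, random mean 3.91%, two-sided p of 0.174). It held 15.7% of Flag-Zmiz1 peaks and 64.6% of Flag-line ICN1 peaks (two-sided p of 0.002 each), and 0 of the 29 low-input ICN1 peaks of that line. Of HA-line ICN1 peaks it held 8.70%, which did not pass (two-sided p of 0.19), and the result turned with the setting: 4 of 382 low-input peaks (1.05%) were below random placement and 13.7% of the peaks at p of 1e-10 or less above it (two-sided p of 0.002 each). HA-Zmiz1 peaks with ICN1 were more often in the library labelled H3K27ac than those without (8.14% and 1.54%, Fisher's exact adjusted p = 1.96e-09), but not among low-input peaks, where the difference was -1.43 points. In the other libraries no difference for HA-Zmiz1 passed by Fisher's exact test, with 92.2% and 93.2% in H3K4me3 (adjusted p = 0.475) and 85.8% and 82.6% in H3K4me1 (adjusted p = 0.283). Without high-input peaks the H3K4me1 difference passed, at 8.08 points. With the upper 50% of segments the differences in H3K4me1 (5.45 points) and H3K4me3 (-8.77 points) passed. With peaks at p of 1e-10 or less, the differences in H3K4me3 (-6.06 points) and in the library labelled H3K27me3 (-8.25 points) passed. These alternatives were judged on the unadjusted p of Fisher's exact test. Flag-Zmiz1 peaks with ICN1 lay in the library labelled H3K27ac in 41 of 41 cases, and those without in 50 of 540 (Fisher's exact adjusted p = 7.04e-37). This rests on high-input peaks, since 0 of 539 low-input Flag-Zmiz1 peaks met a low-input ICN1 peak of that line, and in the upper 50% of segments the difference was -3.67 points.

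**Figure D4:**
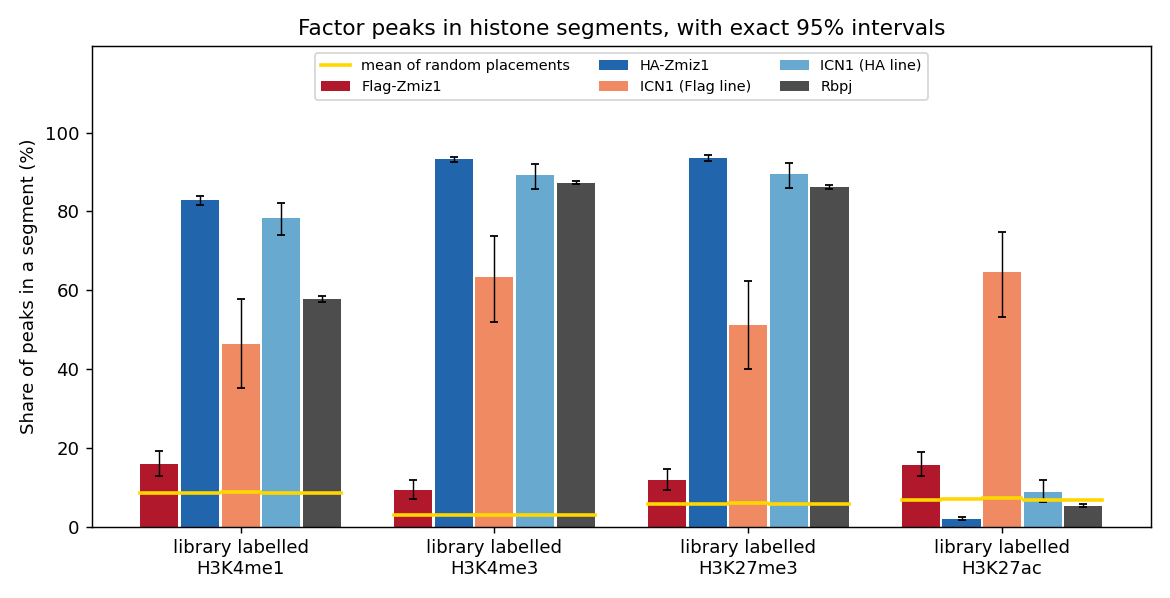
Share of the peaks of each factor list (y axis, %) in segments of each histone library (x axis), with exact 95% intervals and the mean of random placements as yellow lines. HA-Zmiz1, HA-line ICN1 and Rbpj stand at 86.2% or more in the library labelled H3K27me3, and Flag-Zmiz1 at 11.7%.

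The names of the deposited H3K27 data differ from the sample labels, so these labels were checked against genes of known state. Segments of the library labelled H3K27ac covered an end of 26 of 30 developmental regulators, such as Hoxa9 (a 126 kb segment on chromosome 6, fold 6.60) and Hoxb1, and of 0 of 20 housekeeping genes (Fisher's exact adjusted p = 4.51e-10). The library labelled H3K27me3 covered 1 of 30 developmental regulators and 19 of 20 housekeeping genes, such as Actb (fold 7.69), Gapdh and Eef1a1 (Fisher's exact adjusted p = 5.1e-11). By Fisher's exact test, H3K4me3 covered 3 of 30 and 19 of 20 (adjusted p = 1.23e-09), and H3K4me1 2 of 30 and 11 of 20 (adjusted p = 0.000217). Acetylation of H3K27 marks active genes and its trimethylation marks repressed ones, so both libraries went against their labels. Genes of a Hox cluster can lie under the same segment, so the listed genes are not independent in these tests. Hes1 lay under a 22.4 kb segment of the library labelled H3K27ac (fold 5.77).

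**Figure D5:**
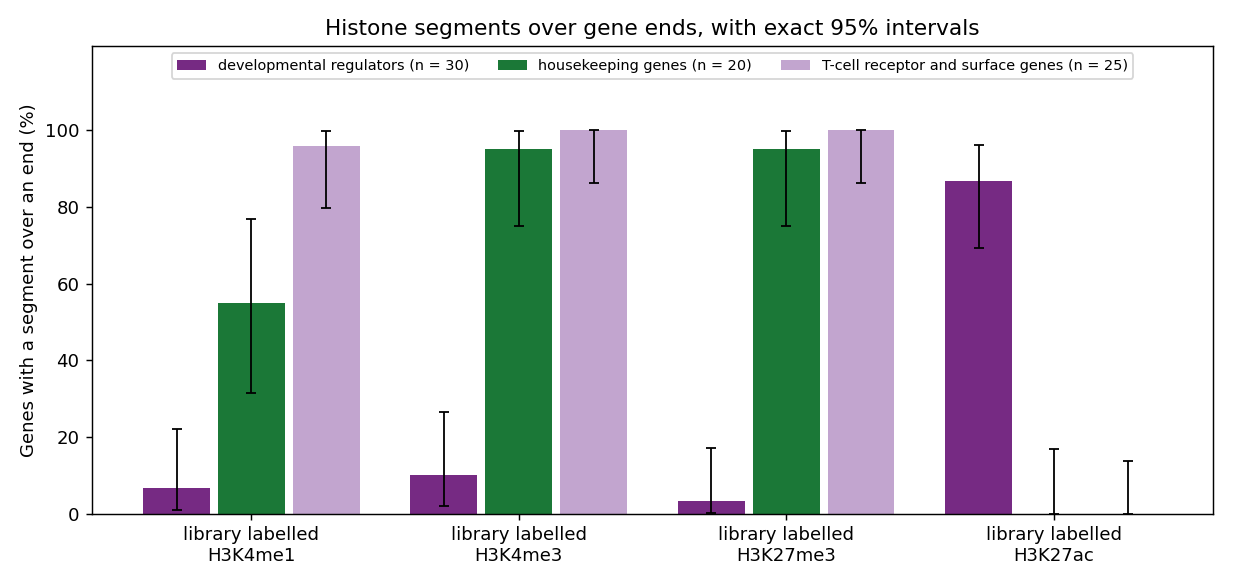
Share of genes (y axis, %) with a segment of each histone library (x axis) over an end, for 30 developmental regulators, 20 housekeeping genes and 25 T-cell receptor and surface genes, with exact 95% intervals. The library labelled H3K27ac covers 26 of the 30 developmental regulators and none of the 20 housekeeping genes.

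Rbpj was the factor most often at gene ends. Within 1 kb of an end lay 44.3% of Rbpj peaks (95% interval 43.6 to 45.0), 18.7% of HA-Zmiz1 peaks (17.6 to 19.8), 15.2% of HA-line ICN1 peaks (11.9 to 19.0) and 5.34% of Flag-Zmiz1 peaks (3.65 to 7.49), against random means of 3.16% to 3.21%. The difference between HA-line ICN1 and HA-Zmiz1 did not pass (Fisher's exact adjusted p = 0.0862), and each differed from Rbpj (adjusted p = 1.46e-35 and 5.39e-262). These lists share many sites: 302 of 414 ICN1 peaks met HA-Zmiz1, and 400 of 414 ICN1 and 3556 of 4984 HA-Zmiz1 peaks met Rbpj. So the same places count on both sides, and these p-values are a rough guide only. Of the Flag-line ICN1 peaks, 0 of 82 lay at an end (random mean 3.30%), which did not pass (two-sided p of random placement 0.11). With 5 kb windows 3.66% lay at an end, which passed below random placement (random mean 12.9%, two-sided p of 0.00799). Of these 82 peaks 53 were high-input, with 11, 11, 9 and 8 of them in single places, while random placement scatters them independently. Among low-input peaks 0 of 29 lay within 1 kb (random mean 2.94%, two-sided p of random placement 0.821), and 5 kb windows were not run on them. So the result cannot be told from where the high-input peaks lie.

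Between the lines, ICN1 sites were shared more often than Zmiz1 sites. ICN1 peaks of the Flag line overlapped HA-line ICN1 at 51 of 82 (62.2%, 95% interval 50.8 to 72.7), and at 22 of 29 among low-input peaks (75.9%, 56.5 to 89.7). Sites at Ctnnd2, Stk3 and Nck2 were among those in both lines. Flag-Zmiz1 overlapped HA-Zmiz1 at 27 of 581 (4.65%, 3.08 to 6.69), and at 2 of 539 among low-input peaks (0.371%, exact 95% interval 0.045 to 1.33, one-sided p = 0.031). By −log10 p, the strongest Flag-Zmiz1 peaks lay in or near Unc5a (chromosome 13, 54970981 to 54971110, fold 46.5), Scrt1 (fold 30.8), Npas4 (fold 21.2), Taf1b and Garnl3, and none of these met an HA-Zmiz1 peak. The strongest HA-Zmiz1 peak lay inside Aff1 (chromosome 5, 103726677 to 103726862, fold 25.1), and others inside Adamts14 and near H2-Q1. The lines differ in tag, Notch1 construct and library, which cannot be separated.

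HA-Zmiz1 peaks with ICN1 were stronger than those without, with median folds of 8.86 (quartiles 6.53 and 11.8) and 6.45 (5.45 and 7.86; permutation p = 1e-05, the smallest possible). HA-line ICN1 peaks with and without HA-Zmiz1 had medians of 6.50 and 6.30, a difference that did not pass (permutation p = 0.32). In the Flag line, shared peaks had lower folds than unshared ones, at 2.91 and 7.39 for Flag-Zmiz1 and 3.13 and 4.87 for ICN1. Fold divides by the local input and all 42 shared ICN1 peaks were high-input (median input ratio 65.2, against 3.22 for the unshared), so lower folds follow from the split. By −log10 p the order in the Flag line was reversed.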

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

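The limit for high-input peaks, the test with lists of equal length and the tests of input, tags, construct, chance and strongest sites were chosen after their results were seen, and those on neuronal genes and on the H3K27 libraries after the patterns had been noticed but before their own values were. The same contrasts came out differently in the lines, by Fisher's exact test on low-input peaks with Benjamini-Hochberg adjustment over 14 tests. The share of ICN1 peaks with a Zmiz1 peak was 0 of 29 in the Flag line and 278 of 382 in the HA line, a difference of -72.8 percentage points (Fisher's exact adjusted p = 7.98e-16). This share is bounded by the Zmiz1 lists, which held 539 and 4952 low-input peaks. With the 539 strongest HA-Zmiz1 peaks it was 121 of 382 in the HA line, a difference of -31.7 points (Fisher's exact p = 3.18e-05). The direction turned with the 100 strongest peaks of each list, high-input peaks kept. There it was 21 of 82 and 16 of 100, a difference of 9.61 points that did not pass (Fisher's exact p = 0.139). Zmiz1 peaks with an Rbpj peak differed by -61.7 points, and ICN1 peaks with an Rbpj peak by -17.3 points (Fisher's exact adjusted p = 0.00104). Zmiz1 peaks differed by -67.7 points in H3K4me1 segments, -88.3 in H3K4me3 segments, -84.1 in those of the library labelled H3K27me3 and 7.74 in those of the library labelled H3K27ac.

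ICN1 and Flag-Zmiz1 peaks overlapped in the Flag line. Reads piled up where the input is high may account for it, since 0% of the 42 shared ICN1 peaks lay outside such regions. The ratio of filtered tags, Flag over HA line, was 1.01 for Zmiz1 and 1.14 for ICN1, so the Flag line did not hold fewer tags. Fewer tags would in any case lower an overlap, so the ratio says nothing about its cause. The Notch1 constructs cannot be told apart from the tag and the library; 75.9% of the low-input ICN1 peaks of the Flag line lay in HA-line ICN1 peaks.

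Flag-Zmiz1 peaks lay apart from HA-Zmiz1 peaks. Of 32 neuronal genes listed before the test, 1 (Snap25, 3.12%) had a low-input Flag-Zmiz1 peak within 50 kb, against 3.73% in random lists, and 2 of 32 liver, muscle and gut genes did. The list left out genes noticed among the peaks, so the test neither supports nor excludes a protein bound at neuronal genes. Calls placed at random over the genome are argued against, as 9.46% of the low-input peaks lay in Rbpj peaks against 0.211% in random placements. Both lists were called against the same input, which random placement does not take into account. So false calls shared through that input are not excluded. The Flag-Zmiz1 list was also not the strongest part of the HA-Zmiz1 list, with 0.371% of low-input peaks shared. The difference of tag, construct and library remains open and untested.

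Of the H3K4me3 segments, 84.7% overlapped the library labelled H3K27me3 and 10.8% that labelled H3K27ac. The gene lists and the check of the labels were fixed before that overlap was seen. The check was planned because the names of the deposited H3K27 data differ from the labels. Its use to weigh explanations came later. An exchange of the samples is a candidate explanation, with developmental regulators 86.7 percentage points above housekeeping genes in the library labelled H3K27ac. In the library labelled H3K27me3 the same difference was -91.7 points. Of the developmental regulators, 3.33% had a segment of the library labelled H3K27me3. Only 3 of 30 had H3K4me3 at an end, so few of them could carry both marks. The check therefore cannot decide whether promoters with H3K27me3 and H3K4me3 together explain the overlap.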

How the results depend on the processing

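The alternatives without high-input peaks, with no matching, with gene length matching, with Zmiz1 lists of equal length and with placement including the library labelled H3K27me3 were chosen after seeing the data; motif comparisons were not run. Of 370 alternatives over 76 results, 324 kept the direction and side of the threshold. The overlap of HA-line ICN1 with HA-Zmiz1 passed under all 8 of its alternatives, at 16.0% (100 strongest peaks) to 73.8%, and the HA-line odds ratio under all 5, at 10.5 to 16.8. Without high-input peaks, 0% of Flag-line ICN1 peaks overlapped Flag-Zmiz1, 0% of HA-line ICN1 peaks overlapped Flag-Zmiz1, the Flag-line odds ratio at Rbpj peaks was 0, the library labelled H3K27ac held 0% of Flag-line and 1.05% of HA-line ICN1 peaks (the latter passed below), and HA-Zmiz1 with ICN1 was -1.43 points from that without in it. No fold comparison was made in the Flag line without them, since no shared peak was left. With both lists cut to their 100 strongest peaks, 0% of Flag-Zmiz1 lay in Rbpj and 0% in HA-Zmiz1 peaks, and the share of ICN1 peaks with Zmiz1, Flag minus HA line, was 9.61 points without passing, high-input peaks kept. In the upper 50% of segments by fold, Flag-Zmiz1 no longer passed at 2.58% in H3K4me3 and 4.99% in the library labelled H3K27me3, and the library labelled H3K27ac held 2.44% of Flag-line ICN1 (did not pass), 0.966% of HA-line ICN1 (passed below) and 3.73% of Rbpj peaks (did not pass). There the Flag-Zmiz1 difference with against without ICN1 was -0.154 points in H3K4me3 and -5.37 in the library labelled H3K27me3. In the library labelled H3K27ac this difference was -3.67 for Flag-Zmiz1 and -0.621 for HA-Zmiz1. Developmental minus housekeeping genes in H3K4me1 was -10 points in these segments, which did not pass. At p of 1e-10 or less, 13.7% of HA-line ICN1 peaks lay in the library labelled H3K27ac (passed above), 1 list was above random lists near HA-line ICN1 in place of 2, and 0 were below near HA-Zmiz1 in place of 1. With 5 kb windows and high-input peaks kept, 3.66% of Flag-line ICN1 peaks were at gene ends (random mean 12.9%, passed below). Lists above random lists were then 1 near HA-Zmiz1 and 0 near HA-line ICN1, in place of 2 each. Lists below were 0 near HA-Zmiz1 and 4 near Rbpj, in place of 1 each. With 200 kb, 1 list was above near HA-Zmiz1. Against all coding genes, 5 were above near Rbpj in place of 0. By −log10 p, shared Flag-line peaks were higher by 6.29 for Flag-Zmiz1 and 8.07 for ICN1. The causes of these changes were not tested, and the removal of high-input peaks used a limit chosen after seeing the data. No replicate could be left out, and the 29 low-input ICN1 peaks of the Flag line limit what could be detected there.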

Other observations

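Within the low-input Flag-Zmiz1 list, the 51 peaks that met an Rbpj peak had a median fold of 9.74, and the 488 others 7.23 (permutation p = 1e-05, the smallest possible; chosen after seeing the data). Of its 5 strongest sites, Scrt1, Npas4 and Garnl3 were of the first kind, and Unc5a, the strongest, and Taf1b were not. Near HA-Zmiz1, 9 of 32 neuronal genes had a peak (28.1%, random lists 27.1%), and 8 of 32 liver, muscle and gut genes did.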
